A study of Danio rerio with 3 samples.

How the data were processed

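The samples were 3 RNA libraries from mpeg1:mCherry and mpx:EGFP zebrafish embryos at 72 hours post fertilization: mCherry+ cells, EGFP+ cells and double-negative cells, 1 library each. Per the labels' protocols, embryos were homogenized, filtered and sorted by flow cytometry, more than 50000 cells were collected for each population, total RNA was extracted with Trizol LS and a carrier, and 50 ng of RNA per library went through ribosomal RNA removal and the SMARTer Universal low-input kit before sequencing on an Illumina HiSeq instrument. The small nuclear RNA gene rn7sk had the highest value in each library (8.45% of the FPKM sum for mCherry+, 10.5% for EGFP+ and 10.3% for double-negative cells). Per the submitters' processing notes, cutadapt, TopHat2 2.0.11, Cufflinks 2.2.1 and the genome build danRer7 were used; their settings, order and the gene annotation are not given in the sources used here. The authors deposited 1 table with an FPKM value (fragments per kilobase of transcript, scaled to library size) for each gene and library, as named by the table. An FPKM is a share of a library, so a few very high genes lower all others in that library.

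The table held 14428 genes with no repeated gene ID; 1004 were listed at 0 in all libraries. The FPKM sums were 571639 for mCherry+, 696949 for EGFP+ and 356886 for double-negative cells. The values were searched for steps of whole reads. Among the 71 to 137 genes low in both libraries of a pair, no single ratio step held more than 5% of the genes. No expected share was computed, so the search cannot tell whether such steps are present. Read depth was not recovered and is unknown, so no counting interval or detection limit is given. The housekeeping gene psmd7 was listed at 0 in every library, so a value of 0 was read only as listed at 0, and no fold against it is printed. Such genes still entered the log2(FPKM + 1) ratios, the counts and the list results, where their ratio depends on the pseudocount. Gene names were taken from the table; 13895 of its gene IDs matched the RefSeq names of assembly GRCz12tu, used for names only because the build differs, and no coordinates are given.

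Ratios were computed as log2 of (FPKM + 1) between libraries, for the 12285 genes with an FPKM of 1 or more in at least 1 library. Genes past a 4-fold ratio were counted in each of the 3 pairs and both directions, and genes at least 4-fold above both other libraries were counted for each library. With 1 library per group there is no residual spread, so these counts rest on a size threshold and carry no test. The housekeeping genes give a sense of scatter: across 49 genes the SD of the log2 ratio was 0.43 for mCherry+ over double-negative, 0.40 for EGFP+ over double-negative and 0.40 for mCherry+ over EGFP+. These SDs, and the median-ratio shifts that follow, were computed from FPKM without a pseudocount. Over 5361 genes with an FPKM of 5 or more in all libraries, the median ratio was shifted by 0.37 for mCherry+ over double-negative, 0.48 for EGFP+ over double-negative and −0.10 for mCherry+ over EGFP+; values are given as deposited, without this correction.

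There were 29 gene lists, with 831 entries of which 650 were found in the table, 37 through an older symbol that is not the current symbol of another gene. They covered macrophage, neutrophil, pan-leukocyte, mmp and timp, cxcl12 axis, ADAM and ADAMTS, stem and progenitor, endothelial, erythroid, skeletal muscle, neuron, photoreceptor and lens, epidermis, fibroblast and matrix, cartilage and notochord, liver, pancreas and gut, pigment, thrombocyte and lymphoid, MHC and antigen, lysosome, complement, NADPH oxidase and redox, inflammatory mediator, chemokine receptor, innate sensing, actin, integrin and migration, cell cycle, dissociation and stress, and housekeeping genes. For each list the median, the mean and the number of members past 4-fold were computed, with the percentile of the median among 10000 random lists of the same size drawn from other genes in the same 20 bins of mean expression. The percentile describes these libraries and is not a test of the populations. The lists, the thresholds, the named-gene rule and the alternatives were fixed before the data were examined.

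Named genes followed a rule: for each pair and direction the 12 genes with the largest ratio among those with an FPKM of 10 or more in 1 of the libraries compared, leaving out clone and locus names and small RNAs; every measured member of the mmp and timp list and the cxcl12 list; up to 4 highest and 4 lowest members of the other lists in the comparison described, with an FPKM of 5 or more; and mpeg1 and mpx. Genes named outside this rule were chosen after their values were seen: rn7sk, psmd7, pmaip1, fos, egr1, si:dkey-10p5.7, nccrp1 and members of the extra lens and muscle lists.

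The steps were tested on simulated data. For mCherry+ over double-negative with 12285 genes and a scatter like that of the housekeeping genes, 98% of 100 genes raised 8-fold and 100% of 100 genes raised 16-fold passed the 4-fold threshold, and 0 unchanged genes did. That scatter is small against the threshold, so these outcomes were set by the simulation. A larger scatter of genes with low values was not simulated, so no rate of false calls follows for the data. Of 60 lists of unchanged genes, 56 had a percentile within the middle 95%. Those lists were drawn at random from the simulated genes, so this share too was set by the simulation. It does not show how percentiles behave for the gene lists used here, some of which share members. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at an FPKM of 10, rescaling to the same FPKM sum, median-ratio and housekeeping scaling, thresholds of 2-fold and 8-fold, and random lists not matched on expression. Alternatives added after the data were seen were the subtraction of carry-over between the reporter libraries and the summing of the 59 genes that share a name with another. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.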

Results

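RNA was profiled from cells sorted out of about 1000 zebrafish embryos at 72 hours post fertilization that carried a pair of fluorescent transgenes. The mpeg1:mCherry transgene marks macrophages and the mpx:EGFP transgene marks neutrophils, the granulocytes rich in myeloperoxidase. More than 50000 cells were collected for each of 3 populations: mCherry+ only, EGFP+ only, and cells with neither reporter (double-negative). Each population gave 1 library, so no value below has a replicate error, no difference was tested against replicate spread, and no p-value is given. The expression table listed 14428 genes in FPKM, and 12285 of them reached an FPKM of 1 in at least 1 library. An FPKM of 1 or more was reached by 10529 genes in the mCherry+ library, 10613 in the EGFP+ library and 11543 in the double-negative library. Read depth was not recovered from the FPKM values and is unknown. Fold and log2 values are on the log2(FPKM + 1) scale, which understates differences of genes with low values. Exceptions are the housekeeping SDs and the shifts of the median-ratio and housekeeping scalings, computed from FPKM without a pseudocount.

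The endogenous genes mpeg1 and mpx, whose promoters drive the reporters, served as a check of the sort. The macrophage perforin-like gene mpeg1 had an FPKM of 1396 in the mCherry+ library, 9.92 in the EGFP+ library and 2.84 in the double-negative library. The myeloperoxidase gene mpx had an FPKM of 12480 in the EGFP+ library, 55.8 in the mCherry+ library and 3.1 in the double-negative library. Each of these endogenous genes was thus highest in the library labelled with the matching transgene. In the mCherry+ library mpx stood at 0.447% of its EGFP+ level, and in the EGFP+ library mpeg1 stood at 0.711% of its mCherry+ level.

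The comparison of mCherry+ with double-negative cells shows which transcripts were higher or lower in the macrophage reporter population than in cells with neither reporter. Of 12285 measured genes, 1005 were at least 4-fold higher and 904 at least 4-fold lower in the mCherry+ library. Of the 1005 higher genes, 526 were also at least 4-fold higher in the EGFP+ library than in the double-negative library. The macrophage list had the highest median of the 29 lists: 22 of its 23 measured members were at least 4-fold higher, with a median log2 ratio of 6.40. The galectin-3-binding protein gene lgals3bpb (FPKM 702 against 0.806), mpeg1, the cathepsin S gene ctssb.1 (1094 against 3.78) and mfap4 (393 against 0.848), a marker used for macrophages, were the highest members, and cd74a, an MHC class II chaperone gene, was the lowest of those above an FPKM of 5 (12.1 against 0.534). Outside that list, irg1, which encodes the enzyme that makes itaconate, reached 3502 against 5.57, the connexin gene cx32.2 reached 738 against 1.30, and havcr1 reached 563 against 0.994.

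Genes shared by leukocytes were also higher in the mCherry+ library. In the pan-leukocyte list 21 of 22 measured members were at least 4-fold higher (median log2 ratio 4.91), among them spi1a, which encodes a PU.1 transcription factor (313 against 1.42), the actin regulator coro1a (562 against 3.60) and cybb, the catalytic subunit of the phagocyte NADPH oxidase (269 against 1.42). The paralog spi1b was at 192 in the mCherry+ library and listed at 0 in the double-negative library. Lysosomal genes followed the same direction, with 27 of 32 at least 4-fold higher and a median of 3.80. The progranulin gene grna (301 against 0.596) and the cathepsins ctsc (660 against 4.35), ctsz (352 against 6.16) and ctsh (95.6 against 1.37) were the highest, while the proton pump subunit gene atp6v1b2 was lower (1.58 against 17.1). The medians were 3.16 for the NADPH oxidase and redox list (10 of 16 at least 4-fold higher), 2.42 for inflammatory mediators (10 of 20, and 0.84 without the filter on low values or 3.50 with a minimum FPKM of 10), 2.39 for MHC and antigen processing (6 of 9, and 1.25 or 3.21 under the same settings), 2.03 for innate sensing (9 of 16, and 3.02 with a minimum FPKM of 10), 1.87 for chemokine receptors (3 of 7, and 4.0 with a minimum FPKM of 10), 1.85 for ADAM and ADAMTS proteases (4 of 8) and 1.83 for actin, integrin and migration genes (10 of 23, and 1 at least 4-fold lower). With a pseudocount of 5 the medians were 0.85 for chemokine receptors and 1.30 for innate sensing, and with 0.1 they were 3.51 and 3.60. Among inflammatory genes, the interleukin gene il1b was at 290 against 1.61 and the cytokine gene csf3 at 531 against 4.38. Tumour necrosis factor tnfa was at 70.4 and listed at 0 in the double-negative library. The toll-like receptor genes tlr21 (51.5 against 0.624) and tlr18 (62.8 against 1.46) were among the highest sensing genes. Neutrophil-list genes were higher as well, 19 of 26 by at least 4-fold with a median of 2.98. The highest were fcer1gl (2011 against 1.73), csf3r (365 against 0.670), ncf1 (313 against 0.975) and rgs13 (88.5 against 1.60). The medians of these lists lay above those of all 10000 random lists matched on expression, except the chemokine receptor list (percentile 99.83) and the ADAM list (99.87). The lists share members, so their results are not independent. For example, the pan-leukocyte list shares coro1a and lcp1 with the actin list and cybb with the NADPH oxidase list. The neutrophil list shares ncf1 and mpx with the NADPH oxidase list, and the macrophage list shares cd74a and cd74b with the MHC list.

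Genes of other tissues were mostly lower in the mCherry+ library. Among liver, pancreas and gut genes 20 of 25 were at least 4-fold lower (median −3.20), such as the apolipoprotein gene apoa2 (37.0 against 1033), transferrin tfa (16.5 against 468) and the fibrinogen gene fga (1.52 against 68.9). The medians were −2.41 for neuronal genes (20 of 27 at least 4-fold lower), −2.31 for epidermal genes (17 of 27), −2.14 for cartilage and notochord genes (11 of 16), −1.90 for photoreceptor and lens genes (12 of 29), −1.44 for pigment cell genes (1 of 19), −1.25 for erythroid genes (8 of 22) and −1.08 for fibroblast and matrix genes (2 of 23). In the pigment cell list csf1ra, which also stands in the macrophage list, went the other way (263 against 0.817). Examples are the RNA-binding protein gene elavl4 (7.87 against 79.4), the intermediate filament gene krt17 (4.32 against 52.0), the cartilage gene ucmab (2.23 against 45.4) and the embryonic globin gene hbae3 (66.6 against 2201). Each of these medians lay below those of all matched random lists except that of the pigment list (percentile 0.05). Skeletal muscle genes were an exception to this direction. Their median was 0.75, at percentile 76.33, and 0.086 with libraries rescaled to the same FPKM sum, and 22 of 27 were above the double-negative level, although the myogenic regulator myod1 was below it (2.99 against 11.5). The medians were −0.54 for endothelial genes (2 of 18 at least 4-fold higher), −0.23 for cell cycle genes (0 of 26 past 4-fold) and 0.84 for genes induced by tissue dissociation and stress (5 of 33 at least 4-fold higher). Medians and means differed in sign for the stem and progenitor list (median −0.69, mean 0.32, 3 of 17 at least 4-fold higher, and a median of 1.46 with a minimum FPKM of 10), the thrombocyte and lymphoid list (−0.42 and 0.35, with 3 of 13 at least 4-fold higher and 1 lower) and the complement list (−0.80 and 0.17). The complement list combined c1qc (146 against 0.723), c1qa and c1qb, higher in the mCherry+ library, with cfb (3.05 against 72.8) and c9 (2.84 against 54.1), lower there. Outside the lists, dap1b was listed at 0 in both reporter libraries and at 270 in the double-negative library.

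Of all calls past 4-fold in this comparison, 52.6% were higher in the mCherry+ library. That share was 36.3% after median-ratio scaling, 39.5% after housekeeping scaling, 26.2% with libraries rescaled to the same FPKM sum, 39.7% with a pseudocount of 0.1 and 45.2% at a 2-fold threshold. It was 75.4% with a pseudocount of 5, 73.6% at an 8-fold threshold and 61.5% with a minimum FPKM of 10. Under the 3 scalings, in the order given, the 904 lower genes became 1391, 1279 and 1884.

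**Figure D1:**
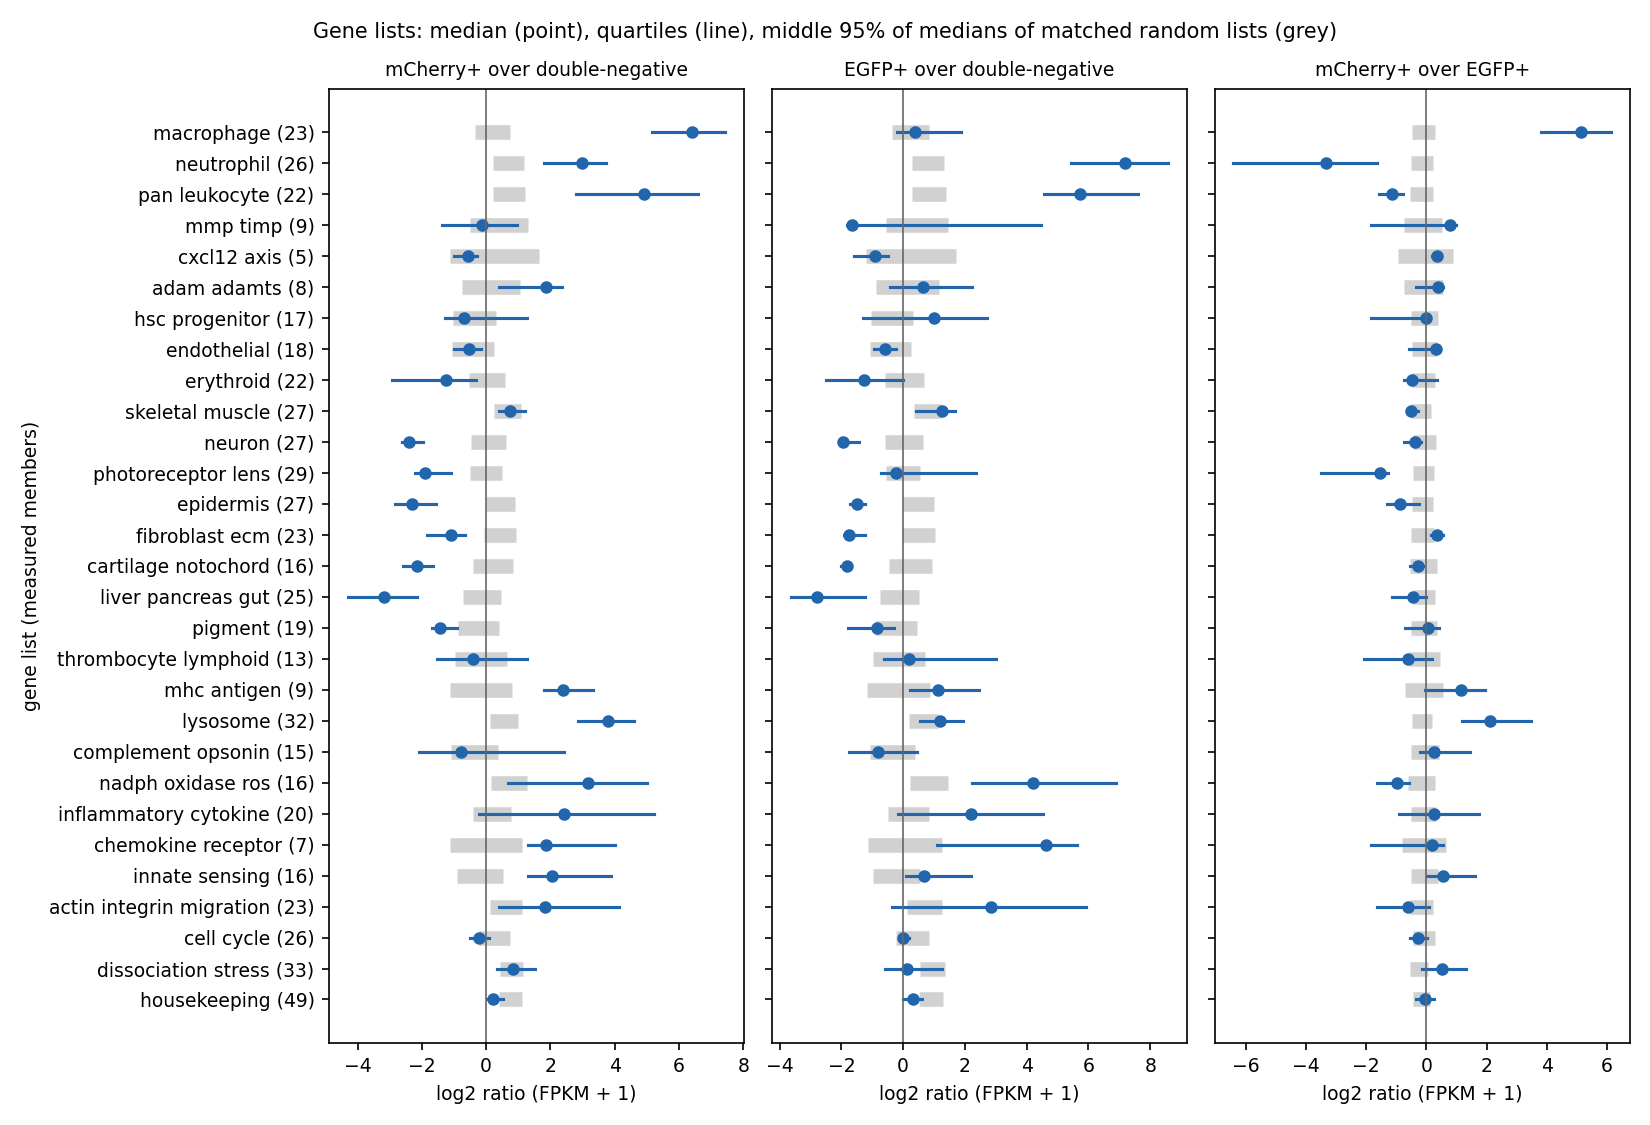
Median log2 ratio (point) and quartiles (line) of the measured members of each gene list, on the log2(FPKM + 1) scale, for mCherry+ over double-negative, EGFP+ over double-negative and mCherry+ over EGFP+ (1 library each). Grey bars span the middle 95% of the medians of 10000 random lists matched on expression; the macrophage median was 6.40 in the left panel and the neutrophil median 7.17 in the middle panel, both to the right of their grey bars.

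The comparison of EGFP+ with double-negative cells asks the same of the neutrophil reporter population. In the EGFP+ library 1048 genes were at least 4-fold higher and 661 at least 4-fold lower. Granule and effector genes of neutrophils were the highest: 25 of 26 measured members of the neutrophil list were at least 4-fold higher, with a median log2 ratio of 7.17. Lysozyme lyz was at 12339.8 against 2.41, mpx at 12480 against 3.1, the astacin-type protease gene npsn at 3644 against 3.42, and fcer1gl at 4832 against 1.73. The member s100a10b was at 127 against 151. The list member scpp8 was at 2313 against 4.94. Outside the list, the genes gmfg (414) and il4 (430) were listed at 0 in the double-negative library.

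All 22 measured pan-leukocyte genes were at least 4-fold higher in the EGFP+ library (median 5.71), among them coro1a (1866 against 3.60), lcp1, which encodes L-plastin (733 against 1.48), and wasb (504 against 0.945). The medians were 4.62 for chemokine receptors (4 of 7 at least 4-fold higher, and a median of 1.1 over all 10 members found, without the filter on low values, or 5.65 with a minimum FPKM of 10), 4.2 for the NADPH oxidase and redox list (12 of 16), 2.85 for actin, integrin and migration genes (14 of 23) and 2.2 for inflammatory mediators (10 of 20, and 0.64 over all 23 members found or 3.40 with a minimum FPKM of 10). The filtered medians were above every matched random list. Examples are ccr9a (382 against 1.78), the sphingosine phosphate receptor gene s1pr4 (99.1 against 0.901), cybb (524 against 1.42), il1b (787 against 1.61), the leukotriene A4 hydrolase gene lta4h (1149 against 12.3) and il10 (136 against 1.17). The lysosome list had a median of 1.18 (5 of 32 at least 4-fold higher and 1 lower, percentile 98.61) and the MHC and antigen list 1.14 (3 of 9, percentile 99.1), which were 0.31 and 0.50 with libraries rescaled to the same FPKM sum, and the MHC median was 0.15 without the filter on low values and 1.91 with a minimum FPKM of 10. The medians were for the innate sensing list 0.67 (4 of 16, percentile 98.89) and for the ADAM list 0.64 (2 of 8, percentile 81.72), the latter −0.20 with libraries rescaled to the same FPKM sum. With a minimum FPKM of 10 they were 1.43 and 1.45. The flagellin receptor gene tlr5b (256 against 3.51) and the adaptor gene card9 (52.7 against 0.293) were the highest sensing genes. The macrophage list had a median of 0.39 (6 of 23 at least 4-fold higher), which was −0.07 with libraries rescaled to the same FPKM sum, and its highest members were ctssb.1 (783 against 3.78), cxcr3.2 (93.6 against 0.988) and lgals9l1 (91.3 against 2.03). In the stem and progenitor list 5 of 17 were at least 4-fold higher (median 0.99, percentile 99.98, and 0.27 with libraries rescaled to the same FPKM sum or 0.38 without the filter on low values, but 3.2 with a minimum FPKM of 10), including csf3r (659 against 0.670), ikzf1 (45.3 against 0.627), cbfb (70.5 against 6.13) and fli1a (65.0 against 6.81), while meis1 was lower (13.5 against 52.8). Of these, csf3r also stands in the neutrophil list, fli1a in the endothelial list and ikzf1 in the pan-leukocyte and lymphoid lists. In the thrombocyte and lymphoid list (median 0.20, 4 of 13 at least 4-fold higher, −0.47 with libraries rescaled to the same FPKM sum and 3.02 with a minimum FPKM of 10) the carboxypeptidase gene cpa5, a mast cell marker, was at 1557 against 17.4.

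Other tissue genes were mostly below the double-negative level in the EGFP+ library too. The medians were −2.78 for liver, pancreas and gut genes (17 of 25 at least 4-fold lower), −1.95 for neuronal genes (9 of 27), −1.83 for cartilage and notochord genes (4 of 16), −1.75 for fibroblast and matrix genes (4 of 23), −1.48 for epidermal genes (2 of 27) and −1.28 for erythroid genes (7 of 22, and 1 at least 4-fold higher). Among them, tfa was at 23.7 against 468, the synuclein gene sncb at 26.3 against 127, the periostin gene postnb at 106 against 522 and hbae3 at 96.3 against 2201. The medians of the pigment list (−0.86, 3 of 19 at least 4-fold lower), the endothelial list (−0.57, 0 of 18, and 1 at least 4-fold higher), the cell cycle list (0.00, 0 of 26) and the stress list (0.13, 0 of 33, and 4 at least 4-fold higher) were closer to 0, and the last pair changed sign to −0.83 with libraries rescaled to the same FPKM sum. The complement median was −0.81 (4 of 15 at least 4-fold lower and 2 at least 4-fold higher), and 0.24 with a minimum FPKM of 10. Skeletal muscle genes had a median of 1.26 (percentile 98.24), which was 0.78 after median-ratio scaling and 0.30 with libraries rescaled to the same FPKM sum, with 24 of 27 above the double-negative level, such as the myosin heavy chain gene myhz1.2 (95.4 against 11.2) and the parvalbumin gene pvalb2 (2512 against 737). The photoreceptor and lens list split: its median was −0.24 and its mean 0.61, and 9 of its 29 members, all lens genes, were at least 4-fold higher. The lens aquaporin gene mipb was at 82.2 against 8.04 and the crystallin gene cryba4 at 112 against 11.8, whereas rhodopsin rho was at 8.71 against 18.9 and the red cone opsin gene opn1lw2 at 97.1 against 185. Globins, keratins, crystallins and muscle myosins belong to families of near-identical paralogs whose reads the quantification could have divided between copies, so single members are uncertain.

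Of the calls past 4-fold in this comparison, 61.3% were higher in the EGFP+ library, against 36.4% after median-ratio scaling, 43.1% after housekeeping scaling, 19.8% with libraries rescaled to the same FPKM sum, 44.4% with a pseudocount of 0.1 and 45.9% at a 2-fold threshold. It was 83.4% with a pseudocount of 5, 79.8% at an 8-fold threshold and 70.0% with a minimum FPKM of 10. Under the 3 scalings the 661 lower genes became 1284, 1077 and 2225. Both reporter libraries were compared with 1 double-negative library: 526 genes were at least 4-fold higher in each, where independent lists would share 85.7, and 398 at least 4-fold lower, against 48.6. Part of either excess may come from the shared library. Simulated libraries without effects shared 0, but their error, set by the spread of housekeeping genes, is too small to reach the threshold, so that value does not show how much the shared library adds.

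The mCherry+ and EGFP+ libraries were compared with each other to separate the reporter populations. In the mCherry+ library 479 genes were at least 4-fold higher and 410 at least 4-fold lower than in the EGFP+ library. Macrophage genes were higher in mCherry+ cells, 20 of 23 by at least 4-fold (median 5.13), and neutrophil genes lower, 16 of 26 by at least 4-fold (median −3.34). The macrophage growth factor receptor gene csf1ra was at 263 against 1.01, lgals3bpb at 702 against 4.28 and havcr1 at 563 against 2.58. The transcription factor gene irf8, needed for macrophage development, was at 105 against 0.565, and c1qc, a complement subunit gene, at 146 against 1.03. On the other side, lyz was at 40.2 against 12339.8, cebp1, a myeloid C/EBP gene, at 1.59 against 406, cpa5 at 5.19 against 1557, il4 at 1.51 against 430 and ctssa at 0.98 against 325. Lysosomal genes were higher in mCherry+ cells, 17 of 32 by at least 4-fold (median 2.11), for example ctsz (352 against 6.87), the legumain gene lgmn (792 against 17.4) and the osteoclast cathepsin gene ctsk (99.8 against 1.63), while cd63 was level (2430 against 2339).

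Smaller list differences between the reporter libraries went both ways. The medians were 1.16 for MHC and antigen genes (2 of 9 at least 4-fold higher in mCherry+, and 0.033 over all 16 members found, without the filter on low values), 0.54 for innate sensing (4 of 16) and 0.51 for stress genes (4 of 33), and −0.97 for the NADPH oxidase and redox list (1 of 16 at least 4-fold lower), −1.16 for pan-leukocyte genes (2 of 22) and −0.60 for actin, integrin and migration genes (3 of 23, and 1 at least 4-fold higher). The MHC class II chaperone gene cd74b was at 37.3 in mCherry+ cells against 1.66, and tlr21 at 51.5 against 0.237. The immediate-early gene jund was at 308 against 51.1. Inflammatory mediators split, 5 of 20 at least 4-fold higher and 4 at least 4-fold lower (median 0.26): irg1 (3502 against 125), tnfa (70.4 against 9.58) and csf3 (531 against 79.5) were higher in mCherry+ cells, and il10 (2.87 against 136) and lta4h (122 against 1149) lower. Among tissue lists the medians were −1.55 for photoreceptor and lens (12 of 29 at least 4-fold lower), −0.87 for epidermis (3 of 27), −0.62 for thrombocyte and lymphoid (4 of 13, and 1 at least 4-fold higher), −0.52 for skeletal muscle (0 of 27), −0.47 for erythroid (1 of 22, and 1 at least 4-fold higher), −0.45 for liver, pancreas and gut (2 of 25, and 1 at least 4-fold higher), −0.36 for neurons (0 of 27), −0.29 for the cell cycle (0 of 26), −0.27 for cartilage and notochord (0 of 16) and −0.03 for the stem and progenitor list (4 of 17). Those above 0 were fibroblast and matrix (0.34, with 1 of 23 at least 4-fold higher), endothelial (0.30, 1 of 18, and 1 at least 4-fold lower), ADAM (0.39, 1 of 8, and 1 at least 4-fold lower) and complement (0.26, 4 of 15, and 1 at least 4-fold lower). The chemokine receptor median was 0.20 with a mean of −0.74, had 0 of 7 members at least 4-fold higher and 2 at least 4-fold lower, and was −1.86 with a minimum FPKM of 10. The pigment median was 0.06 (1 of 19 at least 4-fold higher), and −0.49 with a minimum FPKM of 10. That minimum gave −1.34 for the stem and progenitor list, −2.08 for thrombocyte and lymphoid and −2.33 for photoreceptor and lens. Housekeeping genes had a median of −0.04, which was 0.24 with libraries rescaled to the same FPKM sum, and an SD across 49 genes of 0.40. That list had medians of 0.21 against the double-negative library for mCherry+ and 0.32 for EGFP+, which became −0.45 and −0.61 with libraries rescaled to the same FPKM sum. They stood at percentiles 0.12 and 0.28, because random lists matched on expression had middle values of 0.705 and 0.844, so a percentile compares a list with genes of like abundance and not with 0. The stress median for EGFP+ over double-negative stood at percentile 0.02, against a middle value of 0.90.

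**Figure D2:**
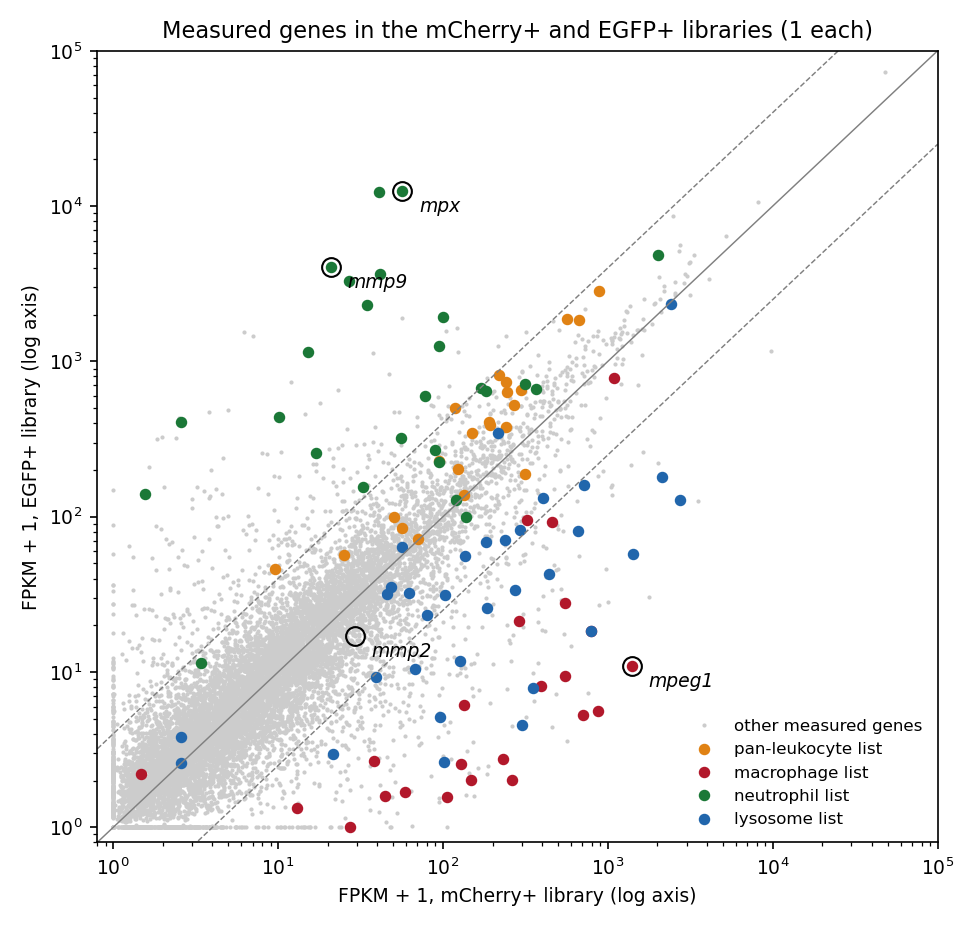
FPKM + 1 of each measured gene in the mCherry+ library (x, log axis) and the EGFP+ library (y, log axis), 1 library each, with members of 4 lists in colour; the solid line marks equal values and the dashed lines a 4-fold difference. Circles mark mpx (55.8 and 12480), mmp9 (19.9 and 4036), mmp2 (28.2 and 16.1) and mpeg1 (1396 and 9.92).

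Genes set at least 4-fold above both other libraries numbered 319 for mCherry+, 281 for EGFP+ and 398 for double-negative cells. The double-negative count was 785 after median-ratio scaling, 674 after housekeeping scaling, 1318 with libraries rescaled to the same FPKM sum, 1007 with a pseudocount of 0.1 and 108 with a pseudocount of 5. The EGFP+ count was 178 with libraries rescaled to the same FPKM sum and 180 with a pseudocount of 5.

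The study's title concerns the matrix metalloproteinases mmp2 and mmp9, the gelatinases that degrade collagen and other matrix proteins, and the libraries show which population carried each transcript. The gelatinase B gene mmp9 had an FPKM of 4036 in the EGFP+ library, 19.9 in the mCherry+ library and 13.2 in the double-negative library. Its log2 ratio was 8.15 for EGFP+ over double-negative and −7.59 for mCherry+ over EGFP+. For mCherry+ over double-negative it was 0.56, which became −0.08 with libraries rescaled to the same FPKM sum, and the mCherry+ value equals 0.494% of the EGFP+ value, near the 0.447% seen for mpx. The gelatinase A gene mmp2 was highest in the double-negative library, at 74.5, against 28.2 in the mCherry+ library and 16.1 in the EGFP+ library. Its log2 ratio was −1.37 for mCherry+ over double-negative and −2.14 for EGFP+ over double-negative, and it stayed below 0 under each scaling tried.

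The other measured members of this family also differed between libraries. Only 9 of the 32 entries of the mmp and timp list were found, so a large part of the family is not covered. The collagenase gene mmp13a resembled mmp9, at 3288 in the EGFP+, 26.0 in the mCherry+ and 3.02 in the double-negative library. The inhibitor gene timp2b was at 645, 181 and 28.3 in the same order, while its paralog timp2a was at 10.2, 21.3 and 35.9. The membrane-type genes were lowest in the EGFP+ library: mmp14a was at 4.84 there, 15.2 in mCherry+ and 16.6 in double-negative cells, and mmp14b at 3.74, 31.3 and 15.7. The genes mmp23bb (0.912 in EGFP+, 2.5 in mCherry+ and 13 in double-negative) and mmp30 (1.26, 0.499 and 6.10) were highest in double-negative cells. Across the 9 measured genes of this list the median and the mean log2 ratio differed in sign in each comparison: −0.12 (0.22 with a minimum FPKM of 10) and 0.05 for mCherry+ over double-negative, −1.65 and 1.17 for EGFP+ over double-negative, and 0.77 and −1.12 for mCherry+ over EGFP+.

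Genes of the cxcl12 axis, the chemokine system that guides blood stem cells to their niche, were measured in the same libraries. The ligand genes were highest in double-negative cells: cxcl12a was at 24.0 there, 9.47 in mCherry+ and 6.55 in EGFP+ cells, and cxcl12b at 36.6, 18 and 11.5. The receptor gene cxcr4b was highest in EGFP+ cells (224), followed by mCherry+ (93.4) and double-negative cells (8.13). The receptor gene cxcr4a was at 2.13, 1.57 and 1.24 in double-negative, mCherry+ and EGFP+ cells, and the scavenger receptor gene cxcr7b at 19.6, 12.9 and 9.99. The median over the 5 genes was −0.57 for mCherry+ over double-negative, −0.91 for EGFP+ over double-negative and 0.34 for mCherry+ over EGFP+, with a mean of opposite sign in the mCherry+ and double-negative comparison (0.05).

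**Figure D3:**
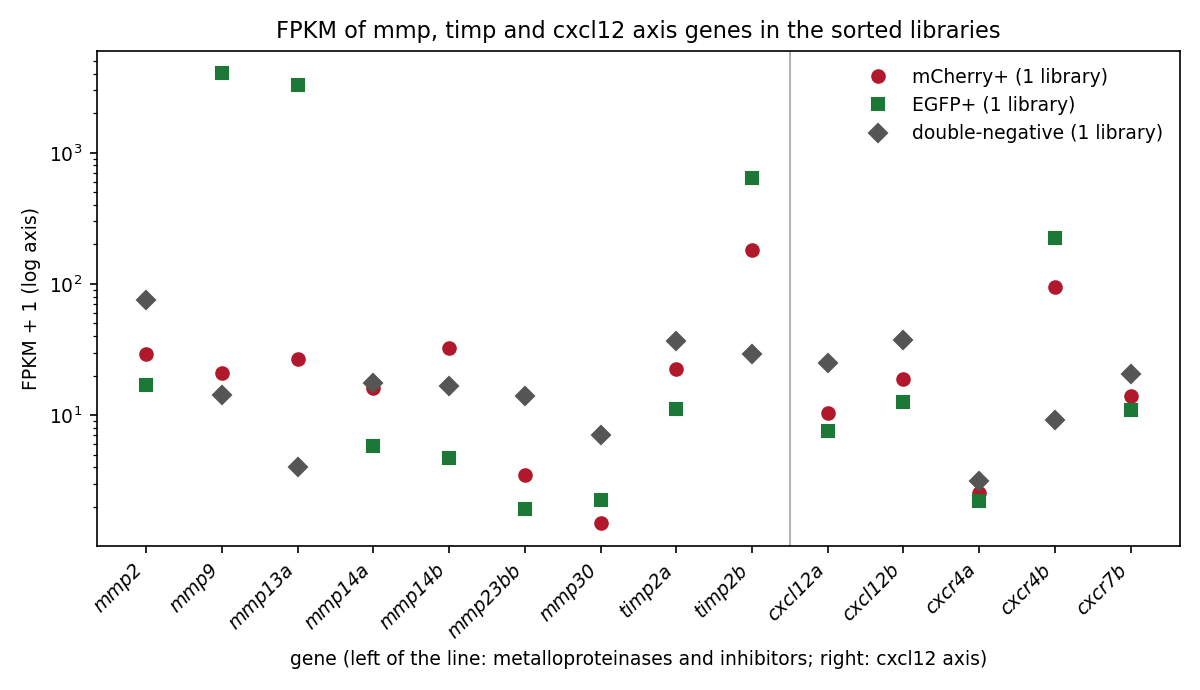
FPKM + 1 (log axis) of the measured metalloproteinase, inhibitor and cxcl12 axis genes in the mCherry+ (circles), EGFP+ (squares) and double-negative (diamonds) libraries, 1 point per library. The EGFP+ values of mmp9 (4036) and mmp13a (3288) stand above all others shown, and mmp2 is highest in the double-negative library (74.5).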

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

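The subtraction of carry-over and the summing of genes that share a name were chosen after the data were seen. No paired analysis was possible because each group had 1 library, and no library could be left out. A value was taken as moved when it differed by more than 1.5-fold from the value in the report. Of the counts, 40 moved and 62 stayed within that range; of the list medians, 105 moved and 591 stayed; of the log2 ratios of named genes, 1135 moved, 2 reversed and 5397 stayed. Reversed means a change of sign of a ratio past 4-fold; counting smaller ratios too, the sign changed in 217 values, among them mmp9 for mCherry+ over double-negative. No count moved with genes that share a name summed or without a filter on low values, and no list median moved after median-ratio or housekeeping scaling. These outcomes were fixed by construction. A gene below an FPKM of 1 in all libraries cannot reach 4-fold with a pseudocount of 1. The log2 shifts of both scalings, at most 0.48, lie below the 1.5-fold limit, so list medians and gene ratios could not move there. The 59 genes that share a name are too few to change a count by 1.5-fold. No gene ID was repeated, so summing repeated IDs had nothing to change. Unknown depth limits the ratios of genes with low values, which depend on the pseudocount. Except where the construction of an alternative is named, the cause was not tested.

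With a pseudocount of 0.1 the counts that moved were 1951 higher in double-negative than mCherry+, 1659 higher in double-negative than EGFP+, 898 higher in mCherry+ than EGFP+, 824 higher in EGFP+ than mCherry+, 1007 above both others in double-negative. The list medians that moved were, for mCherry+ over double-negative 7.47 (macrophage), −1.92 (erythroid), −3.79 (liver and gut), 3.03 (MHC), −2.11 (complement), 3.51 (chemokine receptor), 3.60 (innate sensing). For EGFP+ over double-negative they were 7.85 (neutrophil), 6.32 (pan-leukocyte), −3.56 (liver and gut), 4.31 (inflammatory), 1.32 (innate sensing). For mCherry+ over EGFP+ they were 5.97 (macrophage).

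With a pseudocount of 5, which shrinks ratios of low values by construction, the counts that moved were 651 higher in mCherry+ than double-negative, 212 higher in double-negative than mCherry+, 683 higher in EGFP+ than double-negative, 136 higher in double-negative than EGFP+, 281 higher in mCherry+ than EGFP+, 222 higher in EGFP+ than mCherry+, 180 above both others in EGFP+, 108 above both others in double-negative, 291 higher in both reporter libraries. The list medians that moved were, for mCherry+ over double-negative 4.83 (macrophage), 4.07 (pan-leukocyte), −0.62 (erythroid), −1.77 (neuron), −1.14 (photoreceptor and lens), −2.26 (liver and gut), −0.82 (pigment), 1.63 (MHC), 3.2 (lysosome), 1.44 (inflammatory), 0.85 (chemokine receptor), 1.30 (innate sensing). Those for EGFP+ over double-negative were 5.99 (neutrophil), 4.72 (pan-leukocyte), 0.28 (progenitor), −0.59 (erythroid), −2.15 (liver and gut), 0.80 (inflammatory). Those for mCherry+ over EGFP+ were 4.12 (macrophage).

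Without a filter on low values no count moved, by construction. The list medians that moved were, for mCherry+ over double-negative 5.55 (macrophage), 1.25 (MHC), 0.84 (inflammatory). For EGFP+ over double-negative they were 0.38 (progenitor), 0.15 (MHC), 0.64 (inflammatory), 1.1 (chemokine receptor). For mCherry+ over EGFP+ they were 0.033 (MHC).

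With a minimum FPKM of 10, which leaves fewer genes, the counts that moved were 600 higher in double-negative than mCherry+, 433 higher in double-negative than EGFP+. The list medians that moved were, for mCherry+ over double-negative 1.46 (progenitor), −2.52 (erythroid), 3.21 (MHC), 3.50 (inflammatory), 4.0 (chemokine receptor), 3.02 (innate sensing). Those for EGFP+ over double-negative were 1.45 (ADAM), 3.2 (progenitor), −1.89 (erythroid), −3.37 (liver and gut), 3.02 (thrombocyte and lymphoid), 1.91 (MHC), 0.24 (complement), 3.40 (inflammatory), 5.65 (chemokine receptor), 1.43 (innate sensing). Those for mCherry+ over EGFP+ were −1.34 (progenitor), −2.33 (photoreceptor and lens), −2.08 (thrombocyte and lymphoid), −1.86 (chemokine receptor).

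With libraries rescaled to the same FPKM sum the counts that moved were 669 higher in mCherry+ than double-negative, 1884 higher in double-negative than mCherry+, 548 higher in EGFP+ than double-negative, 2225 higher in double-negative than EGFP+, 178 above both others in EGFP+, 1318 above both others in double-negative, 294 higher in both reporter libraries. The list medians that moved were, for mCherry+ over double-negative −0.76 (mmp and timp), −1.22 (cxcl12 axis), 1.2 (ADAM), −1.13 (endothelial), 0.086 (muscle), −2.98 (epidermis), −1.73 (fibroblast), −2.81 (cartilage), −3.85 (liver and gut), −2.09 (pigment), 3.15 (lysosome), 2.5 (NADPH oxidase), 1.77 (inflammatory), 1.18 (actin), −0.85 (cell cycle), 0.16 (stress), −0.45 (housekeeping). For EGFP+ over double-negative they were 6.43 (neutrophil), 4.88 (pan-leukocyte), −2.46 (mmp and timp), −1.81 (cxcl12 axis), −0.20 (ADAM), 0.27 (progenitor), −1.33 (endothelial), −2.0 (erythroid), 0.30 (muscle), −2.82 (neuron), −1.01 (photoreceptor and lens), −2.38 (epidermis), −2.63 (fibroblast), −2.68 (cartilage), −3.72 (liver and gut), −1.70 (pigment), −0.47 (thrombocyte and lymphoid), 0.50 (MHC), 0.31 (lysosome), 3.26 (NADPH oxidase), 3.71 (chemokine receptor), 1.90 (actin), −0.83 (cell cycle), −0.83 (stress), −0.61 (housekeeping). For mmp2 the log2 ratio was −2.04 for mCherry+ and −3.08 for EGFP+ over double-negative, and for mmp9 −0.081 and 7.22. This alternative lowers the reporter libraries, which have the larger FPKM sums, by construction.

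After median-ratio scaling the counts that moved were 1391 higher in double-negative than mCherry+, 1284 higher in double-negative than EGFP+, 785 above both others in double-negative, and after housekeeping scaling 1077 higher in double-negative than EGFP+, 674 above both others in double-negative.

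At a 2-fold threshold, which admits more genes by construction, the counts were 2445 higher in mCherry+ than double-negative, 2959 higher in double-negative than mCherry+, 2609 higher in EGFP+ than double-negative, 3072 higher in double-negative than EGFP+, 1473 higher in mCherry+ than EGFP+, 1637 higher in EGFP+ than mCherry+. At an 8-fold threshold they were 480 higher in mCherry+ than double-negative, 172 higher in double-negative than mCherry+, 486 higher in EGFP+ than double-negative, 123 higher in double-negative than EGFP+, 217 higher in mCherry+ than EGFP+, 178 higher in EGFP+ than mCherry+.

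With carry-over between the reporter libraries subtracted no count moved. The subtraction took 0.447% of each EGFP+ value from mCherry+ and 0.711% of each mCherry+ value from EGFP+. Shares this small leave most genes nearly unchanged, so the unmoved counts were largely fixed by construction. For mCherry+ over double-negative the log2 ratio reversed for lyz (−1.77) and for mpx (−2.04), the latter by construction, and that of mmp9 was −2.30. For lyz and mpx the subtraction left the lowest value it allows. Their ratios thus reflect that floor and not a measured level below double-negative cells. For mCherry+ over EGFP+ mmp9 had −10.45. The share subtracted was nearly all of the mCherry+ value of mmp9, so both of its ratios depend on a share set by mpx alone. They do not show a measured mmp9 level below double-negative cells, and a share from another gene was not tried. The list medians that moved were, for mCherry+ over double-negative −0.73 (mmp and timp), 2.53 (NADPH oxidase). Those for EGFP+ over double-negative were −0.31 (macrophage).

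Against random lists not matched on expression, 8 percentiles crossed the middle 95% and 79 did not. For mCherry+ over double-negative they were 99.74 (muscle), 26.71 (cell cycle), 99.95 (stress), 89.49 (housekeeping). For EGFP+ over double-negative they were 2.16 (pigment), 96.94 (innate sensing), 73.57 (stress), 94.24 (housekeeping).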

Other observations

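All tests of explanations in this part were chosen after the results were seen. Genes outside the lists also set the reporter libraries apart. In the mCherry+ library, compared with the EGFP+ library, ocstamp, a cell fusion gene of osteoclasts and macrophages, was at 136 against 0.608, the transporter gene abcg2a at 454 against 3.44, the sphingomyelinase gene smpd2 at 154 against 0.602 and the channel gene trpv1 at 184 against 1.21. In the EGFP+ library the kinase gene prkcda was at 486 against 3.94 in mCherry+ cells, ch25hl2 at 209 against 0.657 and gra at 320 against 1.42. The cell death gene pmaip1 was at 9822 in the mCherry+, 1167 in the EGFP+ and 465 in the double-negative library.

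Among stress-list genes, fos and egr1 were chosen after their values were seen: fos was at 1200 in mCherry+, 710 in EGFP+ and 1018 in double-negative cells, and egr1 at 353, 113 and 223. The inhibitor genes nfkbiaa (1215, 955 and 45.4) and nfkbiab (1365, 2264 and 105) were higher in both reporter libraries than in double-negative cells. Among the lowest values, vps4b was at 0.0237 in EGFP+ cells against 63.8 in mCherry+ and 29.5 in double-negative cells.

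Neutrophil-list genes stood above the double-negative level in the mCherry+ library, and RNA or cells carried over from the EGFP+ gate may account for a part of that. If all mpx in the mCherry+ library were carried over, 0.447% of each EGFP+ value would be expected there; of the 19 members at least 4-fold above the double-negative library, that choice alone puts 8 above 3 times this amount plus the double-negative level but none above 4.1 times. Another bound, 5 times, was exceeded by 12 members (5.79 to 101); it was set after the values were seen, and argues against carry-over as their whole source, cebpa being at 139% of its EGFP+ level, while nccrp1, the 1 member between 3 and 5 times (4.81), stays open. The other 6, lyz, mpx, mmp13a, npsn, scpp8 and si:dkey-10p5.7, cannot be told apart from carry-over, since mpx itself sets the share and the others lie within 3 times that level. The mCherry+ FPKM of mmp9 was 1.105 times the mpx share of its EGFP+ level alone, 18 FPKM, and 0.638 times that share plus the double-negative level, 31.2 FPKM, so the hypothesis that it is carried over stays open, as does low expression in the mCherry+ cells themselves, which was not tested.

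Crystallin genes of the lens stood above the double-negative level in the EGFP+ library alone. The 24 measured crystallin genes had a median log2 ratio of 2.04 for EGFP+ over double-negative, with 24 of 24 above 0, and −0.95 for mCherry+ over double-negative. Carry-over of cells like those in the double-negative library cannot lift a transcript above its own source, so the crystallin median argues against it. The double-negative library does not measure free RNA of the homogenized embryos, so this median cannot decide on free RNA. A candidate explanation is that lens cells were collected with the EGFP+ cells: 17 measured lens genes that are not crystallins had a median of 1.28 for EGFP+ over mCherry+, and the 13 of them not already seen had a median of −1.09 for mCherry+ over EGFP+. Of its most abundant genes in EGFP+ cells, mipa (89.2, and 12 in double-negative cells), lim2.4 (87.9 and 17.6) and mipb (82.2 and 8.04) were above the double-negative level and sparc (103 and 370) below it, and mafba, mafa and birc7 were highest in mCherry+ cells; an EGFP gate should remove lens cells unless they fluoresce, and expression by the EGFP+ cells themselves was not tested.

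Skeletal muscle genes had medians above the double-negative level in both reporter libraries, unlike the neuronal and epidermal lists. For mCherry+ the median of 0.75 did not stand apart from matched random lists (percentile 76.33). It was 0.086 with libraries rescaled to the same FPKM sum. The EGFP+ median stood at percentile 98.24. Whole muscle cells in the gates would bring other muscle genes along. The 34 muscle genes outside the sarcomere had a median of −0.50, averaged over both reporter libraries against double-negative cells. Without the members seen before, the medians were −0.52 for mCherry+ and −0.20 for EGFP+. These genes were not matched on expression, on which the middle value of random lists depends. Against double-negative cells, that value was 0.61 for mCherry+ and 0.77 for EGFP+ with lists matched to the skeletal muscle list. For lists matched to the stem and progenitor list it was −0.37 and −0.39, so whole muscle cells stay open. A scale difference between the libraries could contribute and stays open: the list's EGFP+ median of 1.26 was 0.78 after median-ratio scaling and 0.30 with libraries rescaled to the same FPKM sum. Fragments of muscle fibres and taken-up muscle RNA were not tested, and no biological explanation was tested.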
